A study of Mus musculus with 6 samples.

How the data were processed

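Per the labels' protocols, total RNA was extracted with Trizol from ground brain tissue, mRNA was purified on oligo(dT) beads, fragmented and copied with random hexamers, and the amplified product was made into single-stranded DNA circles for sequencing. The labels give 3 young and 3 aged samples, with brain as the tissue and neuroblast as the cell type. The same labels describe a tamoxifen treatment and the measurement of labelled NK cells, and do not relate these to the sequenced RNA. Groups and replicate numbers were taken from the sample titles.

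The authors deposited an expression signal per gene and sample, with 2 decimals and no negative value. The unit of the deposited signal is not named in the file headers or labels, and its normalization, the aligner, the counting tool and the genome build are not given in the sources used here. Per the file headers, the same tables hold the authors' log2 ratio of aged to young and the authors' p-value and q-value, with the test not given in the sources used here. All 88 genes carry the KEGG term for cellular senescence, and the 21 genes of the cell cycle table are identical rows of it that also carry the cell cycle term. No gene had a ratio of group means below 1, and the authors' log2 ratios ran from 0.0185 to 3.21 with 3 genes left blank. The tables were therefore treated as picked for a higher aged mean. No coordinates are given because the build is not given in the sources used here. Both tables were read on one scale because their shared rows are identical, and no pair of sample columns was identical.

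The design written before the data were examined assumed counts or a normalized unit such as FPKM, and the test for the normalized unit was used. Genes with a mean signal of at least 1 over the 6 samples were kept (66 of 88, and 16 of 21 in the cell cycle table), and log2(value + 1) was fitted with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with trend), with no covariate, and Benjamini-Hochberg adjustment within each table at a 5% false discovery rate. Log2 changes are on that scale and understate the change of genes with low values. In all, 26 gene lists were fixed before the data were examined. The 6 with at least 5 tested members were tested with limma's fry, whose directional p asks whether the members move one way and whose mixed p asks whether they change in either direction, and with camera with an estimated correlation. Their mean log2 value per sample was compared by an exact two-sided permutation test, which cannot go below 0.1 for 3 against 3 samples. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 was used for the remaining tests, and matplotlib 3.10.9 for the plots.

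The rule for named genes, also fixed beforehand, took up to 12 genes in each direction past the threshold and without overlap of the groups (0 passed), 23 fixed genes of which 7 were measured, up to 4 members of each list by smallest p and, within the cell cycle table, its members. Of the 45 genes this gave, 27 tested ones are described with values, and Gm8909, Zfp36l1, Traf3ip2, H2-Q4 and H2-T23 were added after their values were seen.

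Alternatives set before the data were examined were equal library medians, a pseudocount of 0.1, no filter or a mean of at least 5, eBayes without trend, limma's array weights, the replicate number as a block, each library left out in turn, a 10% false discovery rate, and an added fold threshold of 1.5. Added after seeing the data were the removal of each library's linear trend on GC content and log2 transcript length, the same without aged replicate 1, and H2-Q6 to H2-Q9 taken as their sum or left out of the MHC class I list. Length and GC content came from the longest coding transcript in GENCODE release M21, matched on the Entrez ID for 80 of 88 genes and 62 of the 66 tested. Relations with GC content and length were tested across genes with 100000 permutations and adjusted over 16 relations.

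The fit was tested on simulated data with the spread of the real libraries and 20 of 66 genes changed, in 50 simulations. With the spread of all 6 libraries, 24.7% of genes changed 2-fold and 81.8% of those changed 4-fold were recovered, and 0.04 genes were called on average when none was changed. With the spread of the 5 libraries without aged replicate 1, 80.0% and 97.8% were recovered. Each simulated set had 3 against 3 libraries, so these shares overstate what a fit of 2 against 3 libraries can recover. The spread was drawn for each gene apart, with no library deviating in many genes at once as aged replicate 1 did. The simulations therefore do not give the recovery or the false calls of the real fits. The depth of the libraries is unknown, so no counting interval is given.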

Results

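Messenger RNA from mouse brain, labelled as neuroblast, was sequenced in 6 samples, 3 from young and 3 from aged brain. Neuroblasts are immature, migrating neurons. The extraction protocol describes ground tissue, and whether cells were sorted is not given in the sources used here. The values analysed were the authors' expression signal for 88 genes of the KEGG pathway for cellular senescence, the lasting arrest of cell division, and for the 21 of these genes that also belong to the KEGG cell cycle pathway. Each of the 88 genes had a higher mean in the aged than in the young samples, so the tables hold genes picked by direction on these same samples, and genes with a lower aged mean were not analysed here. The summed signal of the 88 genes was 2328, 1979 and 1902 in young replicates 1 to 3 and 1900, 2992 and 2943 in aged replicates 1 to 3. The depth of the libraries is unknown. The labels do not say whether the samples came from separate animals, so the p-values measure only the spread between these samples, which may be technical.

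The first comparison asked which senescence genes differed between aged and young brain. Cdkn1a (Entrez gene 12575), a cyclin-dependent kinase inhibitor, was listed at 17.96, 94.6 and 88.0 in aged replicates 1 to 3 and at 30.8, 27.0 and 21.9 in young replicates 1 to 3, or 66.9 ± 42.5 against 26.5 ± 4.46 (SD, n = 3 each). Il1a (16175), which encodes a pro-inflammatory cytokine, was listed at 142, 3.03 and 2.83 in the aged and at 7.50, 5.23 and 3.13 in the young samples, so that its higher aged mean of 49.2 rested on aged replicate 1. The MHC class I gene H2-Q9 (110558) was above all 3 young samples in each aged sample, at 8.78 ± 4.57 against 2.71 ± 0.382 (SD, n = 3 each). Gm8909 (667977), a gene of the KEGG antigen presentation pathway named here after its values were seen, was also above all young samples, at 14.6 ± 8.12 against 4.39 ± 0.930 (SD, n = 3 each).

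None of these differences passed the test. With limma on log2(value + 1), 0 of 66 genes with a mean signal of at least 1 passed a 5% false discovery rate. The lowest adjusted p was 0.444, for Gm8909 (log2 change 1.43, SE 0.381, higher in 3 of 3 aged samples). Gm8909, H2-Q9 (log2 change 1.26, SE 0.424) and H2-Q6 (log2 change 1.29, SE 0.520) were the 3 genes with an unadjusted limma p under 0.05. The fitted log2 change was above 0 for 58 genes, and setting the library medians equal lowered each change by 0.21, which left 24 above 0. H2-Q9, Gm8909, Mdm2 and Zfp36l1, the last also named after its values were seen, were the 4 of 66 genes with all aged samples above all young samples, where chance gives 10% of genes.

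**Figure D1:**
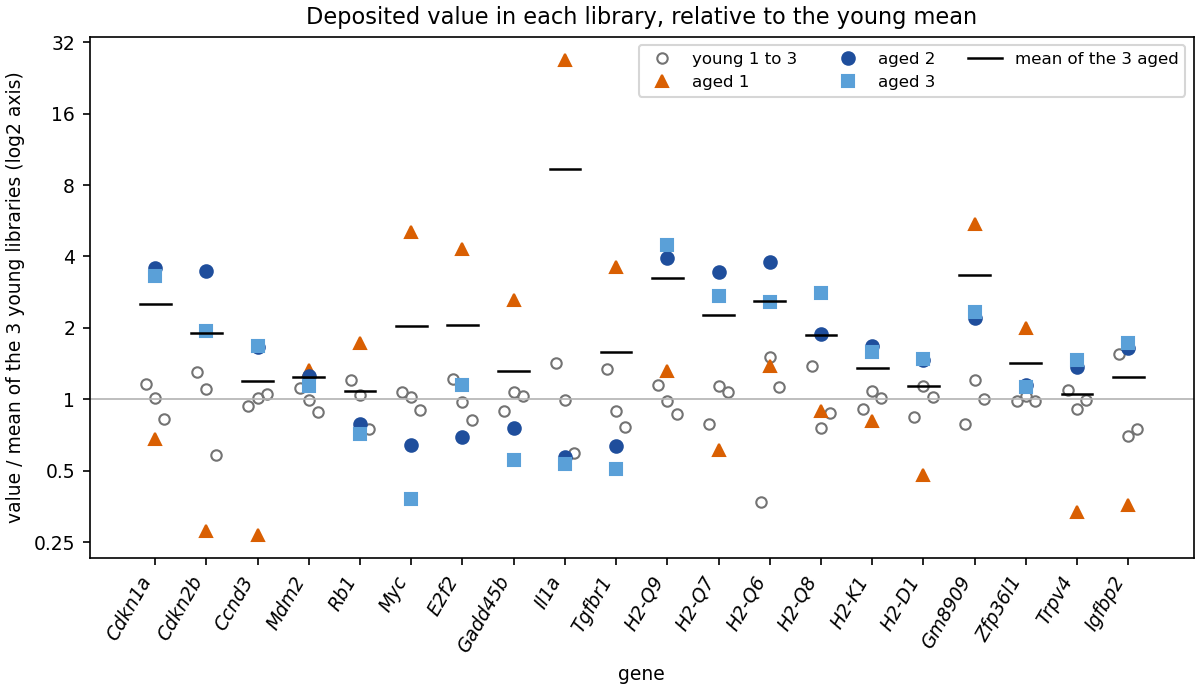
Deposited value of 20 genes in each library divided by the mean of the 3 young libraries, on a log2 axis. Grey circles are the young libraries, coloured symbols the aged libraries and black bars the mean of the 3 aged libraries. Aged replicate 1 lies on the other side of the young libraries from aged replicates 2 and 3 for Cdkn1a, Ccnd3, Myc, Il1a and Tgfbr1. The same holds for H2-K1, Trpv4, Cdkn2b, Gadd45b, H2-Q7, H2-D1 and Igfbp2.

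Aged replicate 1 stood apart from the other 5 libraries. Over the 66 genes, its log2 values correlated with those of aged replicates 2 and 3 at r = 0.737 and 0.723, whereas aged replicates 2 and 3 correlated at 0.992 and the young libraries with each other at 0.962 to 0.992 (Pearson's r across genes, which are not independent replicates). In 53 of the 66 genes, aged replicate 1 deviated from the young mean in the opposite direction to the mean of aged replicates 2 and 3. The selection for a higher aged mean leaves out every gene with both below the young mean. It can therefore raise this count, by an amount that was not tested. Il1a, Myc, Gadd45b and Tgfbr1 were among 6 genes that were above all young samples in aged replicate 1 and below all of them in aged replicates 2 and 3. Tgfbr1, a receptor for TGF-beta, was listed at 164, 28.6 and 23.04 in the aged and at 60.8, 40.4 and 34.4 in the young samples. Cdkn1a, Ccnd3, H2-K1 and Trpv4 were among 21 genes with the reverse order. Ccnd3, a D-type cyclin, was listed at 28.7, 177 and 178 in the aged and at 100.0, 108 and 112 in the young samples.

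**Figure D2:**
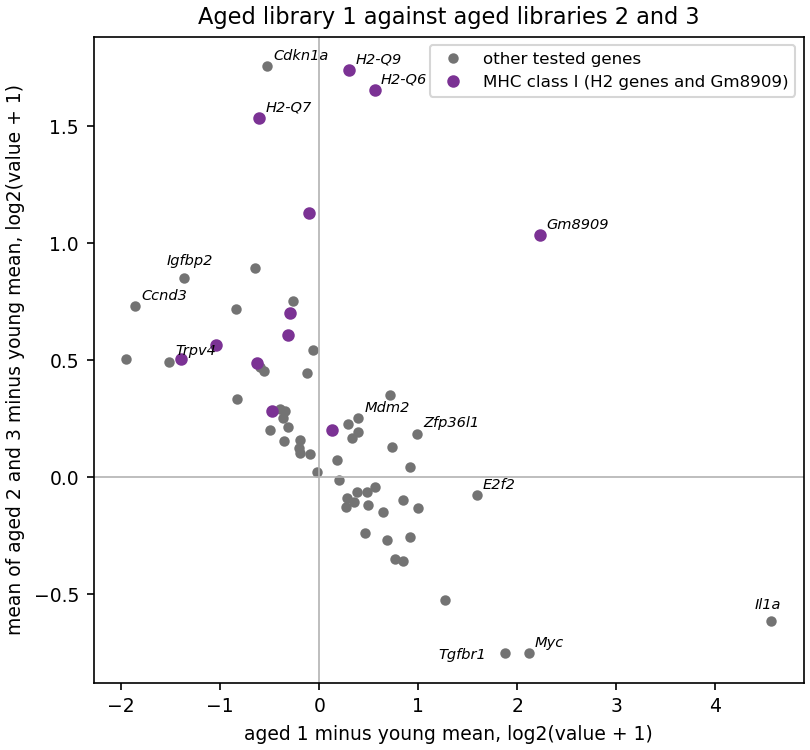
Difference from the young mean on the log2(value + 1) scale in aged replicate 1 (x axis) and in the mean of aged replicates 2 and 3 (y axis) for the 66 tested genes. Each point is a gene, with MHC class I genes (here the H2 genes and Gm8909) in purple. In 53 of the 66 genes the differences have opposite signs, as for Cdkn1a and Il1a, and Gm8909, H2-Q9, Mdm2 and Zfp36l1 lie above 0 on both axes. The genes were picked for a higher aged mean, which can raise the count of opposite signs.

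The count of genes depended on that library. Without aged replicate 1, limma called 15 of the 66 genes, 14 higher and 1 lower in the aged samples, and without any single other library it called 0. The genes were picked for a higher mean of all 3 aged samples. Where aged replicate 1 lay below the young mean, as for Cdkn1a, Ccnd3 and H2-K1, the mean of aged replicates 2 and 3 had to lie above it. The directions and p-values of this fit are thus partly set by the selection. Cdkn1a was then higher by a log2 change of 1.76 (SE 0.158, limma adjusted p = 0.000511, range over its alternatives 0.000175 to 0.999) and H2-Q9 by 1.74 (SE 0.198, adjusted p = 0.00126, range 0.000175 to 0.999), in 2 of 2 aged samples each. H2-Q7, H2-Q6, H2-Q8, Gm8909, Cdkn2b, Ccnd3, Traf3ip2, H2-K1, H2-Q4, H2-D1, Trpv4 and H2-T23 were higher by log2 changes of 0.49 to 1.66, and Myc, a growth-promoting transcription factor, was lower by −0.75 (SE 0.224). Traf3ip2, H2-Q4 and H2-T23 are named here after their values were seen. Across the 62 tested genes with an annotated coding transcript, aged replicate 1 minus the mean of aged replicates 2 and 3 fell with GC content (Spearman's rho −0.553, Pearson's r −0.546, permutation p = 1e-05, the smallest the permutations can give, adjusted p = 3.2e-05 over 16 relations). Young replicate 1 minus the mean of young replicates 2 and 3 gave a rho of −0.553 (Pearson's r −0.482) with the same permutation p, but with length a rho of 0.147 (Pearson's r 0.116, permutation p = 0.254, adjusted p = 0.313). The mean of aged replicates 2 and 3 minus the young mean rose with GC content (rho 0.587, Pearson's r 0.536) and fell with transcript length (rho −0.575, Pearson's r −0.493), with a permutation p of 1e-05 and an adjusted p of 3.2e-05 each. Over the 52 genes left without MHC class I genes (H2 and Gm symbols), rho was 0.531 with GC content and −0.527 with length. Their permutation p was 8e-05 and 9e-05, with an adjusted p of 0.00018 each. Aged replicate 1 minus the mean of aged replicates 2 and 3 rose with length (rho 0.48, Pearson's r 0.381, permutation p = 0.00015, adjusted p = 0.000267). For the mean of all 3 aged minus the young mean, neither relation passed, with GC content (rho −0.047, Pearson's r 0.057, permutation p = 0.716, adjusted p = 0.764) or with length (rho −0.206, Pearson's r −0.225, permutation p = 0.106, adjusted p = 0.154). These permutation p-values treat genes as independent, which they are not, and do not measure the spread between libraries. With the GC and length trend of each library removed, limma without aged replicate 1 called 6 of 62 genes. The trend was fitted on all 62 genes, the called ones included, which can itself shrink the changes of those calls. Of the 13 earlier calls that have a GC value, 4 remained, namely Cdkn1a, H2-Q7, Gm8909 and Traf3ip2, each with a smaller log2 change than before. That of Gm8909 went from 1.04 (SE 0.215) to 0.63 (SE 0.133). The other 2 calls were Mdm2, higher by a log2 change of 0.41 (SE 0.0767), and Gadd45b, lower by −0.90 (SE 0.146), both of the p53 pathway list. Of the 9 that no longer passed, 8 had a smaller log2 change than before, such as H2-K1 (0.70, SE 0.130, before and 0.40, SE 0.106, after) and H2-Q6 (1.66, SE 0.462, before and 1.45, SE 0.480, after). Myc had a larger one, at −0.88 (SE 0.208).

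MHC class I genes, which present peptides on the cell surface, made up the largest of the gene lists fixed beforehand, with 21 members in the table and 11 tested. None of the 11 passed over all genes tested, and 0 passed when adjusted over the list alone. H2-K1, a classical MHC class I heavy chain, was listed at 129, 268 and 252 in the aged and at 145, 172 and 162 in the young samples. H2-D1, another classical heavy chain, was listed at 113, 346 and 352 in the aged and at 199, 271 and 242 in the young samples, and its log2 change of 0.03 (SE 0.546) became −0.18 with equal medians. In 10 of the 11 genes aged replicates 2 and 3 were above all young samples, while aged replicate 1 was below all of them in 7. Of all 66 tested genes, 25 had aged replicates 2 and 3 but not 1 above all young samples. A further 4 had all aged samples above them. The list's directional test gave an adjusted p of 0.443 with limma's fry and its mixed test 0.883, and the mean log2 difference was 0.45 (exact permutation p = 0.4). It was 0.24 (exact permutation p = 0.5) with the related copies H2-Q6, H2-Q7, H2-Q8 and H2-Q9 counted as their sum and 0.13 (exact permutation p = 1) with these left out. With 1 library left out it ran from 0.25 (without aged replicate 2) to 0.86 (without aged replicate 1).

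Without aged replicate 1, 8 of the 11 MHC class I genes passed the 5% threshold, each higher in the aged samples. When adjusted over the list alone, 9 passed. The fitted log2 change of the others was also above 0. The list then passed fry with an adjusted p of 0.00543 (range over its alternatives 0.00543 to 0.815) and a mixed adjusted p of 0.000973, with an adjusted p = 0.255 with an estimated correlation against the other genes. With the 4 H2-Q copies summed, 4 of 8 members passed, with a fry adjusted p of 0.0197, and with them left out 3 of 7, with 0.029. The tables hold genes picked for a higher aged mean, so these counts are not independent evidence of direction. With GC and length trends removed as well, the directional test gave 0.0721 and the mixed test 0.0167. The mean log2 difference was then 0.54 over the 8 members with a GC value, against 0.86 over all 11 before. The shift thus reflects the smaller set of members as well as the correction, which was fitted with these members included. Of the 6 called members with a GC value, H2-Q7 (log2 change 1.19, SE 0.155) still passed, while H2-Q8 and H2-Q9 have no GC value and were not in that fit. H2-Q6, H2-Q7, H2-Q8 and H2-Q9 are related copies whose reads the authors' counting could have split, so their single values are uncertain. Their sum was 23.4, 78.5 and 71.6 in the aged and 21.6, 27.4 and 24.9 in the young samples (57.8 ± 30.0 against 24.6 ± 2.92, SD, n = 3 each, exact permutation p = 0.3).

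The p53 pathway list had 5 tested members. Mdm2, the ubiquitin ligase that limits p53, was listed at 22.2 ± 1.73 in the aged and 17.95 ± 2.12 in the young samples (SD, n = 3 each), higher in 3 of 3 aged samples. Gadd45g, a stress-response gene, was listed at 25.2 ± 6.06 against 20.8 ± 4.28, and its relative Gadd45b at 8.96 ± 7.78 against 6.84 ± 0.645 (SD, n = 3 each), with 17.9 in aged replicate 1 and 5.19 and 3.78 in aged replicates 2 and 3. The list mean was 4.10, 4.35 and 4.03 in the aged and 3.97, 3.84 and 3.64 in the young samples on the log2 scale. That difference of 0.34 had an exact two-sided permutation p of 0.1, the smallest that 3 against 3 samples allow, and 0.6 after adjustment over 6 lists. Cdkn1a is 1 of the 5 members, and the exact permutation p was 0.2 without aged replicate 1, aged replicate 2 or young replicate 3 and 0.3 with equal medians or with GC and length trends removed (0.5 with these removed and without aged replicate 1). The list's fry adjusted p was 0.443, with 0 members past the threshold over all genes and 0 adjusted over the list alone. Without aged replicate 1 its mixed test passed (adjusted p = 0.00783, range over its alternatives 0.00286 to 0.994), while its directional test gave 0.246. Camera gave an adjusted p = 0.974 with an estimated correlation, and Cdkn1a was the 1 member past the threshold (3 with GC and length trends removed as well, Gadd45b among them as lower).

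The other 4 lists with at least 5 tested members had a fry adjusted p of 0.443, with 0 members past the threshold over all genes or adjusted over the list alone. Among 7 DNA damage response genes, the kinase genes Atm and Atr were highest in aged replicate 1, at 2.92 and 4.16 against young means of 1.66 and 1.94, and Rad1 was listed at 8.38 ± 2.58 against 6.32 ± 1.35 (SD, n = 3 each). Among 9 RAS, MAPK and PI3K genes, the deacetylase gene Sirt1 was listed at 4.79 ± 1.58 against 3.52 ± 0.578, and the kinase gene Mapk12 at 13.4 ± 9.40 against 13.1 ± 2.63 (SD, n = 3 each). Among 8 calcium and calcineurin genes, Calml4 was listed at 58.2 ± 21.4 against 44.0 ± 20.6 (SD, n = 3 each). Trpv4, a calcium-permeable channel, was listed at 18.4, 74.7 and 80.2 in the aged and at 60.0, 49.9 and 54.5 in the young samples. The mean log2 differences of the DNA damage, RAS, calcium and pocket protein lists were 0.19, 0.04, 0.07 and 0.12, and each turned negative when the library medians were set equal. With 1 library left out they ran from 0.10 (without aged replicate 1) to 0.30 (without aged replicate 3) for DNA damage, from −0.011 (aged replicate 2) to 0.10 (aged replicate 1) for RAS, from 0.019 (young replicate 3) to 0.15 (young replicate 1) for calcium and from 0.0013 (aged replicate 1) to 0.18 (aged replicate 3) for pocket protein genes. Without aged replicate 1 and with GC and length trends removed, they were 0.35 for DNA damage, 0.19 for RAS, 0.23 for calcium and 0.088 for pocket protein genes. Fry's mixed test then passed for DNA damage (adjusted p = 0.00286), RAS (0.0128) and calcium (0.0195), but not for pocket protein genes (0.0596). The directional test passed for none of them.

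Lists with fewer members at a mean of at least 1 are described without a group test; with no filter on low values the cyclin list had 5 members, with a fry adjusted p of 0.227 and a mixed adjusted p of 0.929. Among secreted factors, Igfbp2, which binds insulin-like growth factors, was listed at 170, 776 and 814 in the aged and at 733, 329 and 353 in the young samples. The NF-kB subunit gene Rela was listed at 64.4 ± 25.8 against 63.4 ± 12.1 (SD, n = 3 each). The lists of microglia, NK and T cell, astrocyte, oligodendrocyte, endothelial, neuroblast, neural stem cell and mature neuron markers, and those of DNA replication, anaphase-promoting complex, cohesin, polycomb and histone genes, had 0 members in the tables.

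The second comparison asked the same of the 21 cell cycle genes, of which 16 had a mean of at least 1. Cdkn2b, an inhibitor of the cyclin D kinases, was listed at 0.29, 3.63 and 2.04 in the aged and at 1.37, 1.16 and 0.61 in the young samples. Myc was listed at 22.4, 2.83 and 1.67 against 4.73, 4.51 and 3.97, and E2f2, a transcription factor of the cell cycle, at 6.55, 1.05 and 1.75 against 1.84, 1.47 and 1.24. Rb1, the retinoblastoma gene, was listed at 11.5 ± 6.05 against 10.7 ± 2.47, and the cyclin gene Ccna2 at 1.71 ± 1.02 against 1.10 ± 0.460 (SD, n = 3 each). Limma within this table called 0 of 16 genes, with a lowest adjusted p of 0.944 and 0 genes at an unadjusted p under 0.05. Adjusted over the lists alone, 0 of the 2 CDK inhibitors, 0 of the 2 tested cyclins and 0 of the 6 pocket protein and E2F genes passed. Without aged replicate 1, Cdkn1a, Cdkn2b and Ccnd3 were higher and Myc was lower in the aged samples (4 genes, limma adjusted p from 9.91e-06 to 0.0207), and without any single other library 0 genes passed. The selection for a higher aged mean partly sets the direction of the genes that were higher. The count was 7 with GC and length trends removed as well, and 1 with array weights on all 6 libraries. The cyclin and checkpoint genes Ccnb2, Ccne1, Ccne2 and Chek1 had means below 1 and were not tested, which left the mitosis list, with Ccnb2 as its single member, untested.

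The authors' deposited table gave much smaller p-values for the same genes. In it, 54 of the 85 genes with a log2 ratio had a q-value under 0.05, among them 15 cell cycle genes and 47 of the 66 genes tested here. The authors' deposited table listed a p-value of 0 for Il1a, Cdkn1a and Tgfbr1, with log2 ratios of 3.21, 1.38 and 0.62. Of those 54 genes, 39 had aged replicate 1 on the other side of the young mean from the mean of aged replicates 2 and 3, and 4 had all aged samples above all young samples. The selection for a higher aged mean can raise that count of 39. The authors' log2 ratios in the deposited table followed the log2 ratio of the group means of the signal (Pearson's r = 0.995 across 85 genes, median absolute difference 0.025).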

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

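The removal of GC and length trends, the sum or omission of the H2-Q copies and the count of other splits were chosen after the results were seen. Over all settings in which all 6 libraries were weighted equally, limma called 0 genes in the senescence table and 0 in the cell cycle table and fry, where run, 0 lists by its directional or mixed test. That holds for equal medians, a pseudocount of 0.1, no filter, a mean of at least 5, eBayes without trend, a 10% false discovery rate, a fold of at least 1.5, GC and length trends removed, and the H2-Q genes summed. Leaving out 1 library at a time gave 0 to 15 genes in the senescence table, 0 to 4 in the cell cycle table, 0 to 1 list by fry's directional test, 0 to 2 by its mixed test and 0 to 1 list at the smallest exact p possible, with every gene and fry call coming from the fit without aged replicate 1. Array weights, which gave aged replicate 1 a weight of 0.07, called 15 genes, 13 of them shared with the fit without that library, and 1 cell cycle gene, 1 list by the directional and 2 by the mixed test. GC and length trends removed without aged replicate 1 gave 6 genes, 7 cell cycle genes, 0 lists by the directional and 5 by the mixed test of fry, and 2 lists at the smallest exact p, against 1 in the values as deposited. That number was also 2 with equal medians (the calcium and RAS lists, lower in the aged samples) and 2 with no filter (the p53 and cyclin lists, higher). Calls in the settings that only drop or down-weight aged replicate 1 follow from that library, and for the other shifts, those with GC and length trends removed as well included, the cause was not tested. With the replicate number as a block, 0 genes, 0 cell cycle genes and 0 lists by either fry test passed. Each number occurs once in each group, so the block cannot alter a log2 change, only its test. Same-numbered samples deviated together at r = 0.271, 0.091 and 0.408. That was the highest r of aged replicates 1 and 3 with a young library. Aged replicate 2 had its highest with young replicate 3 (0.254). These values do not settle whether the samples are paired. The titles do not say that the numbers pair samples, so they were not read as pairs.

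Equal medians lowered each log2 change by 0.21 and, as the tables hold genes picked for a higher aged mean, also remove part of that selection. Changes then became −0.19 for Rb1, −0.18 for H2-D1, −0.082 for Tgfbr1, −0.0044 for Myc, −0.13 for Gadd45b, −0.10 for Igfbp2, −0.048 for Atm, −0.0084 for Traf3ip2 and −0.091 for H2-T23, and list means −0.13 for calcium, −0.019 for DNA damage, −0.089 for pocket protein and −0.16 for RAS genes. The RAS list was −0.016 with a mean of at least 5 and −0.011 to 0.10 with 1 library left out. Array weights gave −0.29 for Rb1, −0.44 for Il1a, −0.59 for Tgfbr1, 0.66 for Ccnd3, −0.71 for Myc, −0.55 for Gadd45b, 0.52 for Trpv4, 0.40 for Mapk12 and 0.22 for Rela. Removing GC and length trends gave −0.0078 for Gadd45b and, without aged replicate 1, −0.42 for Il1a, −0.29 for Tgfbr1, 0.42 for Ccnd3, −0.88 for Myc, −0.069 for Gadd45g, −0.90 for Gadd45b, 0.27 for Trpv4, −0.14 for E2f2, 0.26 for Mapk12 and 0.057 for Rela. With 1 library left out, log2 changes ran from −0.041 to 0.27 for Atm, −0.10 to 0.45 for Atr, −0.57 to 0.73 for Ccnd3, −0.029 to 0.89 for Cdkn2b, −0.077 to 0.86 for E2f2, −0.52 to 0.47 for Gadd45b, −0.25 to 0.57 for H2-D1, −0.089 to 0.49 for H2-T23, −0.28 to 0.85 for Igfbp2, −0.62 to 1.99 for Il1a, −0.76 to 0.50 for Mapk12, −0.75 to 0.81 for Myc, −0.35 to 0.24 for Rb1, −0.27 to 0.33 for Rela, −0.75 to 0.64 for Tgfbr1, −0.13 to 0.72 for Traf3ip2 and −0.54 to 0.49 for Trpv4. The other 14 named genes kept their direction in every setting that gave them a value. The block, eBayes without trend and the filters on low values cannot alter a gene's log2 change, so they add nothing to that. The genes were also picked for a higher aged mean.

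The 6 samples can be split into 3 and 3 in 10 ways, too few for a share under 0.05. As large a result came from 10 of the 10 splits for each count, since the real split gave 0 genes, 0 cell cycle genes and 0 lists, and the highest of the other splits gave 1, 0 and 2.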

Other observations

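All tests in this part were chosen after the result they bear on was seen.

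Aged replicate 1 deviated from aged replicates 2 and 3 by an SD of 1.38 over the 62 genes with a GC value. The tables were picked for a higher mean of these same aged libraries, which can itself set them against each other and was not tested. The highest correlation of aged replicate 1 with a young library was 0.844, and the lowest between young libraries was 0.962. That argues against a wrongly labelled young sample that resembles the young libraries. It cannot exclude a young sample that itself deviates. Aged replicate 1 still correlated more with each young library (0.807 to 0.844) than with aged replicates 2 and 3 (0.737 and 0.723). The selection for a higher aged mean can also alter these correlations, by an amount that was not tested. A swap with a sample from outside the series stays open. A linear trend on GC content and length of the longest coding transcript may account for part of the deviation, but not the whole. Removing it left an SD of 1.15, 5.77 times the SD of aged replicate 2 minus 3 (95% bootstrap interval 4.11 to 7.41). Trends of another shape, or on other transcripts, were not tested. A different make-up of cell types cannot be told apart from a change within the cells, since 0 markers of the 8 fixed cell type lists are in the tables.

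The authors' p-values may come from reads with counting error only, with no term for the spread between samples. If so, each p-value and log2 ratio imply a number of reads per unit of signal. That number should grow in proportion to transcript length if the signal is also length-scaled. Over 48 genes the slope on log scales was 0.996 (95% bootstrap interval 0.909 to 1.07), with a median of 16.0 implied reads per unit and kilobase (quartiles 14.4 and 16.3). That slope is what counting error together with a length-scaled unit such as FPKM would give. It bears on both assumptions at once, so both remain hypotheses, about the authors' test and about the unnamed unit.

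Cdkn1a and 10 of the 11 tested genes of the MHC class I list were above all young samples in aged replicates 2 and 3. Of all 66 tested genes, 25 had aged replicates 2 and 3 but not 1 above all young samples. A further 4 had all aged samples above them. The selection for a higher aged mean can raise these counts. Gm8909, outside that list, was above all young samples too but highest in aged replicate 1 (24 against 9.63 and 10.25 in aged replicates 2 and 3). Reads split differently among H2-Q6, H2-Q7, H2-Q8 and H2-Q9 are argued against by their sum. It was at least 2.91 times the young mean in both aged replicates 2 and 3. The sum covers only these copies, so reads shared with other MHC class I genes were not tested. Linear GC and length trends were fitted on 51 other genes and removed. Cdkn1a in aged replicates 2 and 3 then stayed above the highest young library by 1.21 on the log2 scale, more than the young range of 0.611. A linear trend is thus not the whole cause for Cdkn1a, and trends of another shape were not tested. For the 8 MHC class I genes with a GC value, the gap of the list median was 0.30 before and 0.0691 after, within the young range both times (0.333 and 0.352), so this test decides nothing and a GC and length trend stays open for them. Age stays open and untested: a higher Cdkn1a level with age, absent from aged replicate 1, is consistent with these values as a hypothesis that further aged samples would have to test.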
